A study of Pseudarthrobacter psychrotolerans with 2 samples.

How the data were processed

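Pseudarthrobacter psychrotolerans YJ56, a soil actinobacterium, was grown on R2A, a nutrient-poor medium, and RNA was taken in the mid-exponential phase. There was 1 library for the culture at 13 °C, which the series design calls the control, and 1 library for the culture at 25 °C. Per the labels' protocols, RNA was purified with RNeasy columns and libraries were made with a stranded TruSeq mRNA kit. The temperatures are those of the sample titles and the series design. The growth protocol in the labels names 13 °C for both alternatives.

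The authors deposited 1 table of 4847 genes, with raw read counts for each library, per the file headers. Per the submitters' processing notes, Bowtie2 was used, without a version. The counting program, its strand setting, the genome build and the annotation are not given in the sources used here, so reads of overlapping or antisense genes could not be separated. The table gives no start, end or strand, and genes are located here by replicon (the chromosome or 1 of the plasmids the table numbers 2 and 3) and by their order. The authors also deposited a second value per gene and library that no header names. It behaves as FPKM, reads scaled by depth and by an effective gene length. In 426 genes with more than 2000 reads in each library and an effective length above 600 bases, the effective length was 7.48 bases longer in the 25 °C library (SD 0.07 over genes). The authors deposited p-values from DESeq2 and edgeR too, per the file headers. Whether these were adjusted, and how spread was estimated from 1 library per temperature, is not given in the sources used here.

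All 15 rRNA and 51 tRNA genes were listed at 0 in both libraries, and the step behind this is not given in the sources used here. The 69 RNA genes were left out of the comparison, as was 1 gene that is not reported here. Of 4777 protein-coding genes, 73 had no read in either library. The 3998 genes with at least 50 reads in 1 or both libraries were measured. Of these, 440 are annotated as frameshifted, incomplete or with an internal stop. Further, 49 gene symbols are used more than once, and these genes are given with their feature number in the table. Reads of near-identical copies could be split or shared by the counting, and 43 measured genes repeat the counts and product of another gene.

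Counts were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3 over protein-coding genes (0.828 for 13 °C and 1.21 for 25 °C). The log2 ratio of 25 °C over 13 °C was taken with 0.5 added to each count. A gene was called higher or lower at a 2-fold difference. With 1 library per temperature there is no replicate check on any difference, and no p-value was computed. Folds carry exact conditional binomial 95% intervals and shares carry exact Clopper-Pearson 95% intervals. These cover counting error only, not spread between cultures. They can be too narrow even for that, since reads amplified by PCR are not independent molecules. Against a library with no read, the fold was taken against a floor of 3 counts.

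There were 31 gene lists, defined by patterns in product names and symbols before the data were examined. The product text searched included the KEGG name where the table gave one. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on abundance in 10 bins, and lists outside the middle 95% are said to lie outside the range of random lists. That percentile describes these libraries and is not a test of temperature. Random lists draw genes singly, while members of a list can be neighbours that differ together, so the random range can be too narrow. With 31 lists, 1 or more can lie outside by chance. Functional categories given in the table (eggNOG letters) with at least 10 measured genes were treated alike. Runs were sets of at least 3 adjacent measured genes called in the same direction, counted also in 1000 random gene orders.

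Several list patterns took in genes of another function. The secretion pattern was faulty: it matched the ending of words such as acetate and aspartate, and 49 of its 69 measured members have another function by their annotation. In 12 lists such members were dropped by further patterns, written after the values had been seen. The lists as first defined are reported, and those without the dropped members are given beside them where the percentile moved by more than 5 or crossed a limit, and for the secretion list.

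The genes named are the 12 largest ratios in each direction among genes with a named product, the 1 largest hypothetical gene in each direction, the highest, lowest and most abundant member of each list, the 5 longest runs in each direction, and the 10 most abundant genes of each library. Several runs of 6 genes tied for the last of the 5 places in each direction, and the first in gene order was taken. The text names a selection of the list members. Alternatives covered the scaling (total counts, DESeq2 1.42.0 size factors, the deposited FPKM), the read filter, the added count, the threshold, copies, frameshifted genes and list membership. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. The steps were tested on simulated data, with counts drawn from the real means for this comparison. Of 3911 genes in that step, all 34 with a 2.5-fold higher and all 32 with a 2.5-fold lower simulated level were called, and 0 of 3707 unaltered genes were. The simulation holds counting error and no spread between cultures. It raised and lowered nearly equal numbers of randomly picked genes and left the rest unaltered. It therefore cannot show which scaling is right for the real libraries.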

Results

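The transcriptome of the cold-adapted strain YJ56 was measured at 13 °C and 25 °C, with 1 library per temperature. The table held 10987384 counts at 13 °C and 13896510 at 25 °C. Protein-coding genes took 7556420 of these (68.8%, 95% interval 68.7 to 68.8) at 13 °C and 6419884 (46.2%, 46.2 to 46.2) at 25 °C. Nearly all other counts fell on ssrA, the transfer-messenger RNA that rescues stalled ribosomes, and rnpB, the RNA of ribonuclease P. The 10 most abundant protein-coding genes took 18.0% of protein-coding counts at 13 °C and 10.9% at 25 °C. Both sets included dnaK, a pair of groL genes and grpE (protein folding), tuf and fusA (translation elongation), and GU243_07055, an ATP synthase subunit.

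The comparison asks how gene expression differs between growth at 13 °C and at 25 °C. Among the genes with the largest ratios, hutH of histidine breakdown, the threonine dehydrogenase gene GU243_23080 and the phosphate-binding protein gene pstS were higher at 25 °C. The amino acid permease gene GU243_14980 and the branched-chain amino acid permease genes GU243_22440 and GU243_22435 were lower. Of 3998 measured genes, 530 were at least 2-fold higher at 25 °C and 597 at least 2-fold lower, and 104 and 136 differed by at least 4-fold. No difference has a replicate check. The split depends on the scaling: with total protein-coding counts every log2 ratio lies 0.54 higher, and 1166 genes were higher and 264 lower, so that 81.5% of called genes were higher against 47.0% with TMM. Without the 20 most abundant genes in the total, the counts were 941 and 335 (73.7% higher). Directions below are relative to TMM scaling.

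**Figure D1:**
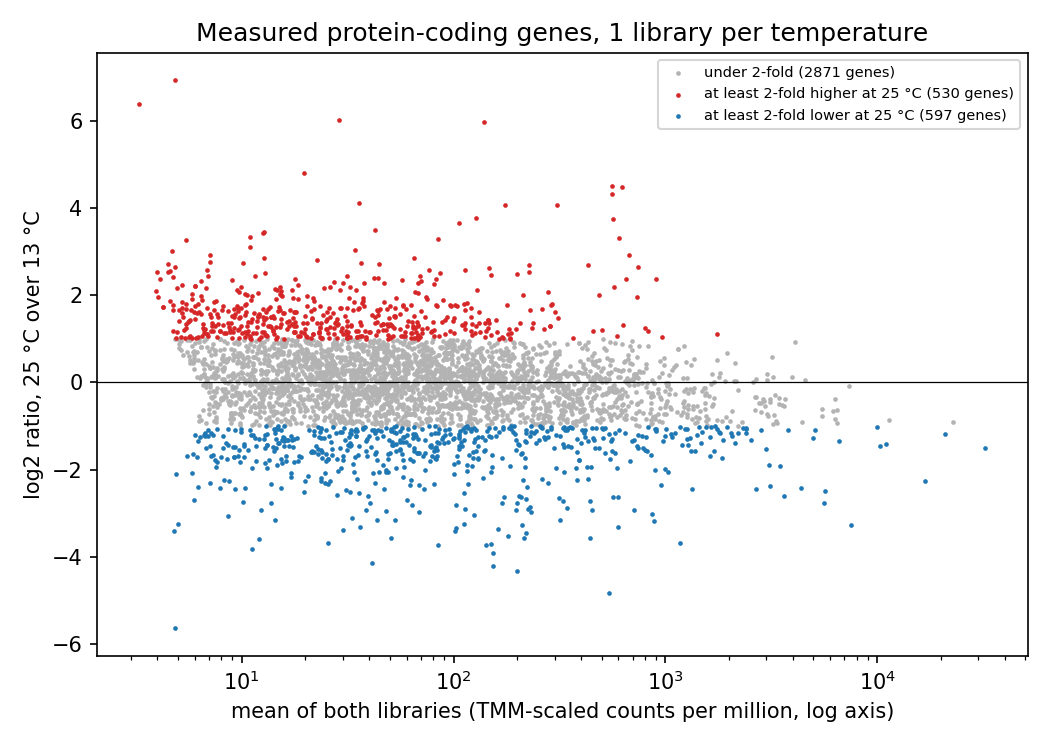
Each point is 1 of the 3998 measured protein-coding genes, with the mean TMM-scaled count level (CPM) of both libraries on a log axis against the log2 ratio of 25 °C over 13 °C. The 530 red genes are at least 2-fold higher and the 597 blue genes at least 2-fold lower at 25 °C, with 1 library per temperature.

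Histidine ammonia-lyase (hutH) and urocanate hydratase (GU243_18460), which open the breakdown of histidine, were 22.3-fold (95% counting interval 20 to 25.0) and 20.2-fold (18.1 to 22.6) higher at 25 °C. A formimidoylglutamase of the same pathway, hutG (feature 5232), was 17.7-fold higher (11.7 to 27.8) on 24 and 525 reads. Another formimidoylglutamase, hutG (feature 7412), differed less, with 266 and 774 reads and a log2 ratio of 1.23. GU243_18455, a helix-turn-helix protein gene beside GU243_18460, was 63.6-fold higher (43.6 to 96.7). GU243_13060, of the same domain and beside hutG (feature 5232), was 71.4-fold higher on 5 and 442 reads (30.4 to 221). L-threonine dehydrogenase GU243_23080 (16.9-fold) and glycine C-acetyltransferase GU243_23085 (13.4-fold), which together turn threonine into glycine, lay beside GU243_23090, annotated as D-arginine dehydrogenase (16.8-fold). The gene ald (feature 6630), annotated as a transhydrogenase, was 22.6-fold higher, and the ATPase GU243_17865 was 29.8-fold higher on 8 and 295 reads. The frameshifted recombinase GU243_09020 had 0 and 51 reads, and the hypothetical gene GU243_23245 had 0 and 75 reads. Against the floor of 3 counts they were at least 13.7-fold and at least 20.2-fold higher, and their counting intervals, which also cover the error of the 25 °C count, began at 10.8 and 16.0.

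Lower at 25 °C were the amino acid permease GU243_14980 (28.5-fold, 25.3 to 32.3), the sodium/solute symporter GU243_01225 (20-fold, 17.0 to 23.8) and the citrate symporter GU243_23050 (13.1-fold, 8.87 to 20). The branched-chain amino acid permeases GU243_22440 and GU243_22435 were 18.6-fold and 13.2-fold lower, and the neighbouring ATP-binding GU243_22430 was 13.0-fold lower. The glutamine synthetase GU243_11185 was 17.8-fold lower (12.6 to 26.1), hisC, annotated for histidine synthesis, 15.2-fold (12.9 to 18.1), the permease GU243_19295 14.7-fold and the fumarate reductase GU243_22090 13.4-fold. Next to the permease GU243_14980, the frameshifted or incomplete aldehyde dehydrogenase GU243_14975 was 12.9-fold lower. The hypothetical gene GU243_00845 was 11.9-fold lower. One of the genes named dusB (feature 9298) had 60 and 1 reads, a ratio of 74.3 with a counting interval from 12.8 to 2980. This ratio rests on 1 read at 25 °C, and whether reads were split with the other gene of that symbol was not tested.

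Of 36 measured genes of nitrogen metabolism, 15 were at least 2-fold higher at 25 °C, 4 lower and 17 between. Their median log2 ratio of 0.57 lay at percentile 99.97 of random lists. The highest was GU243_22865, an FAD-dependent oxidoreductase (6.78-fold, 5.17 to 9.04). The most abundant glutamine synthetase, glnA (feature 984), was 2.14-fold lower. Of 53 peptidoglycan and cell wall genes, 6 were higher, 1 lower and 46 between, with a median of 0.17 (percentile 99.7). Over all measured genes 13.3% were higher and 14.9% lower, so this list held few lower genes and no excess of higher ones. Its matched random lists had a median of -0.20. N-acetylmuramoyl-L-alanine amidases, which cut the cell wall, stood at both ends, with GU243_10100 5.02-fold higher and GU243_02185 2.73-fold lower.

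Aromatic compound degradation had 3 of 42 measured genes higher and 12 lower at 25 °C, with a median of -0.70 (percentile 0.01). The lowest was GU243_17510 (6.55-fold lower, 5.40 to 8.0), while the most abundant, paaK of phenylacetate breakdown, was 1.23-fold higher. Of 46 genes of glycolysis and the pentose phosphate pathway, 3 were higher and 14 lower, with a median of -0.59 (percentile 0.15). The glyceraldehyde-3-phosphate dehydrogenase gap was 3.76-fold lower (3.68 to 3.84), and GU243_18235, a 1-phosphofructokinase, was 3.85-fold higher. Total scaling adds 0.54, which leaves both medians below 0, but that of glycolysis only just. With TMM the counting interval of the glycolysis median was -0.70 to -0.46, and adding 0.54 puts 0 inside it. The sign of the glycolysis median under total scaling is therefore not settled. The interval of aromatic degradation, -0.75 to -0.58, stays below 0 after the same step.

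Among 16 heat shock chaperones and proteases, 0 were at least 2-fold higher at 25 °C and 7 were lower, with a median of -0.88 (percentile 1.84). The most abundant protein-coding gene of either library, dnaK, was 2.83-fold lower (2.81 to 2.85), its exchange factor grpE 2.73-fold lower, and the Clp protease GU243_05960 3.32-fold lower. The percentile was 3.20 with a filter of 200 reads, inside the range of random lists. It was 3.88, also inside, with members found by product name or symbol, without the KEGG names of genes with a product name. Of 25 genes of fatty acid synthesis and desaturation, 1 was higher and 10 lower, with a median of -0.53 (percentile 2.09). The frameshifted or incomplete acyl-CoA desaturase GU243_01850, of a family that introduces double bonds into fatty acids, was 10.2-fold lower (8.91 to 11.8). The more abundant desaturase GU243_12590 was 1.45-fold lower, a log2 ratio of -0.54. Total scaling adds 0.54, which leaves almost no difference in this gene. The highest member, GU243_07350, is annotated as a methyltransferase. The list came inside the range of random lists with a filter of 200 reads (percentile 3.93) and without its 2 methyltransferases (3.13). Under total scaling the median of this list was 0.010, the opposite sign.

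The secretion list had 3 of 69 members higher and 15 lower, with a median of -0.42 (percentile 0.62), which total scaling turns to 0.13. Its lowest member, acs (feature 4908), is an acetate-activating enzyme, its highest, GU243_14265, a tungstate importer and its most abundant, acnA, the aconitase of the citric acid cycle. The 20 members left after dropping such genes, chosen after the values were seen, had 0 higher and 7 lower, with a median of -0.79 (percentile 0.38). The polyphosphate and phosphate uptake list had 4 of 23 members higher and 2 lower, with a median of -0.01 (percentile 61.1), and pstS was 12.8-fold higher (10.4 to 15.8). Its 14 members left by the same later step had a median of 0.55 (percentile 99.3).

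All other lists lay inside the range of random lists with the main settings. Of 5 cold shock proteins, 1 was higher, 2 lower and 2 between (percentile 19.3). GU243_21945 was 7.5-fold lower at 25 °C (6.47 to 8.73), GU243_07020 3.22-fold higher, and the most abundant, GU243_18805, 1.38-fold lower, but higher under total scaling. Of 23 genes of RNA helicases and RNA turnover, 1 was higher and 2 lower, and the helicase GU243_14405, annotated as DeaD, was 3.45-fold lower (3.25 to 3.68). Of 52 ribosomal proteins, 0 were higher and 10 lower, with a median of -0.67 (percentile 2.92). This position passed the lower limit with the deposited FPKM (2.17) and with a filter of 10 reads (1.22). Of 25 translation factors, 1 was higher and 8 lower (percentile 12.4, and 3.30 without the 5 members of another function), with tuf 2.27-fold and obgE 3.82-fold lower. Of 27 respiratory chain genes, 4 were higher and 5 lower (percentile 43.6, and 27.6 without 3 such members). GU243_02570, a subunit of a quinol oxidase, was 5.15-fold higher (4.86 to 5.47), and atpE of the ATP synthase 2.24-fold lower.

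Of 17 genes for compatible solutes, which protect cells from osmotic stress, 3 were higher and 5 lower (percentile 29.8). The trehalose-phosphatase GU243_15005 was 6.0-fold higher and choline dehydrogenase betA 4.02-fold lower. The 39 oxidative stress genes had 2 higher and 6 lower (percentile 3.44), with the ferroxidase GU243_14305 5.71-fold higher. The citric acid cycle list had 2 of 35 higher and 5 lower (percentile 2.76, and 20.3 for the 16 members that are left when genes of other pathways are dropped). Sigma factors and their regulators had 6 of 18 higher and 2 lower (percentile 40.4), with GU243_01080 6.92-fold higher on 16 and 137 reads. Mobile elements had 15 of 100 higher and 4 lower (percentile 95.4), toxin-antitoxin genes 5 of 13 and 0 (82.4), and iron uptake 1 of 9 and 4 (7.82). Sugar transport had 1 of 10 higher and 2 lower (29.8), sulfur assimilation 0 of 11 and 4 (36.4), and DNA repair 3 of 33 and 0 (89.8).

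The others were general stress proteins (3 of 15 higher, 2 lower, percentile 54.1), branched-chain amino acid synthesis (0 of 16 and 2, 38.1), isoprenoid synthesis (0 of 9 and 0, 60.7), DNA topology (0 of 8 and 1, 89.9), pili and motility (2 of 7 and 1, 27.1), glycogen metabolism (0 of 11 and 1, 18.8), aminoacyl-tRNA synthetases (1 of 22 and 1, 43.8) and the synthesis of histidine, tryptophan and arginine (0 of 29 and 1, 39.6, and 59.7 without 3 members of another function). With a filter of 200 reads the median of pili and motility went from -0.05 to 1.52 (percentile 97.52), just outside the range of random lists. That median rests on fewer than the 7 members, the most abundant of which, cpaB (feature 3629), had 145 and 878 reads. It does not describe the list as a whole.

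**Figure D2:**
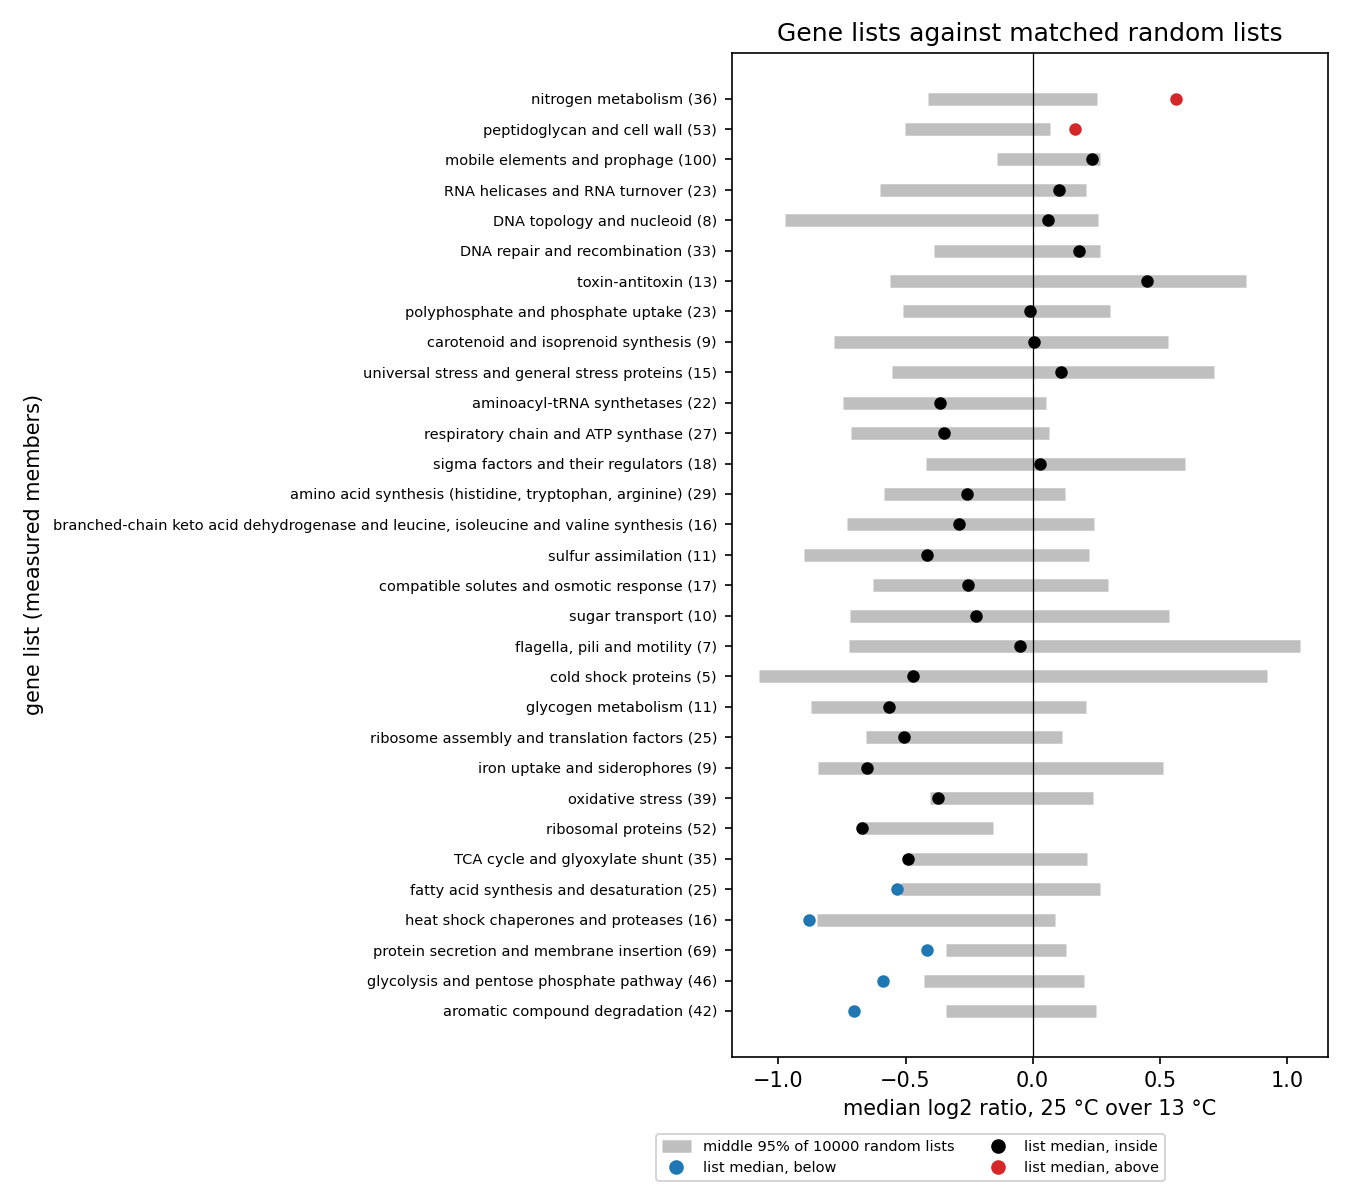
Each dot is the median log2 ratio of 25 °C over 13 °C of 1 of the 31 gene lists, with its number of measured members in parentheses, and grey bars span the middle 95% of 10000 random lists matched on abundance. Nitrogen metabolism (0.57) and peptidoglycan (0.17) lie above their bars, and 5 lists, among them aromatic degradation (-0.70) and glycolysis (-0.59), lie below. With total scaling all medians lie 0.54 higher.

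Genes that differed lay together along the replicons. There were 50 runs higher at 25 °C, holding 210 genes, against a median of 8 and at most 18 in 1000 random orders, and 60 runs lower, holding 248 genes, against a median of 11 and at most 23. With total scaling, which called 1166 genes higher and 264 lower, there were 141 higher and 29 lower runs. Random orders were not counted for that scaling. The longest higher run held 13 genes, from GU243_11240 to GU243_11300, with log2 ratios from 1.21 to 3.31. It contained gcvH, gcvT and gcvP of glycine cleavage, glycine hydroxymethyltransferase, L-serine ammonia-lyase, lipoyl synthase, a methylenetetrahydrofolate reductase and the transporter cycA. The next held 8 genes with phosphotransferase proteins, 1-phosphofructokinase and a pair of trehalose phosphorylase genes. Runs of 7 genes held xanthine dehydrogenase, urate hydroxylase pucL and purine permeases (1.03 to 3.05), and urease accessory genes with a nickel transporter (1.13 to 2.29). One of several runs of 6 held hutG (feature 5232), a heme-transporting ATPase and an alcohol dehydrogenase, among others, between helix-turn-helix protein genes. Another run of 6 held hutH and the urocanate hydratase GU243_18460.

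The longest lower runs held 9 genes each. In GU243_00820 to GU243_00860 (-3.56 to -1.43) lay an amino acid deaminase, a sugar kinase, the aldolase eda and a solute transporter, and in GU243_21375 to GU243_21415 (-3.92 to -1.11) lay hisC, sulfoacetaldehyde acetyltransferase and an amino acid permease. Runs of 7 held acyl-CoA dehydrogenases and related enzymes (GU243_03760 to GU243_03790, -3.40 to -1.10), and formyl-CoA transferase with fumarate reductase (GU243_22065 to GU243_22095, -3.74 to -2.17). One of several runs of 6, from GU243_05100 to GU243_05125, held triokinase and ribose-5-phosphate isomerase.

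By the functional categories of the table, lipid metabolism (letter I, 2 of 110 higher and 26 lower, percentile 0.10) and translation (J, 8 of 152 and 24, 0.33) lay below random lists. Transcription (K, 58 of 295 and 22, 99.95) and replication and repair (L, 28 of 220 and 11) lay above, the last above all 10000. Over all measured genes 13.3% were higher and 14.9% lower, so category L held few lower genes and no excess of higher ones. Its median log2 ratio of 0.23 was also that of the mobile elements list, and members shared with that list were not counted. The DNA repair list lay inside the range of random lists (percentile 89.8). In the authors' deposited table, 155 protein-coding genes had a DESeq2 p-value under 0.05, of which 54 were higher and 101 lower at 25 °C, and 245 had an edgeR p-value under it, 113 higher and 132 lower. Values from 1 library per temperature compare those libraries, not the conditions.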

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

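The rRNA test and the 13 °C comparison in the background test were chosen after results had been seen. The RNA genes ssrA and rnpB are listed here because they held reads in both libraries but were left out of the protein-coding comparison, which says nothing of a difference between the temperatures. The share of ssrA was 25.4% of all counts at 13 °C and 43.6% at 25 °C, and that of rnpB 5.81% and 10.2%.

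Both RNAs took a larger share at 25 °C by nearly the same factor, 1.72 for ssrA and 1.75 for rnpB, with ssrA to rnpB ratios of 4.37 and 4.29. If shorter fragments favoured short RNAs, short genes might show it, but 388 short genes lay 0.13 above 2007 long ones of like abundance on the log2 scale (95% bootstrap interval 0.03 to 0.26), under 0.41, which is 50% of the log2 ratio of ssrA. This argues against a bias by gene length of that size, but the length of a gene need not be that of its transcript, whose ends the table does not give, so a bias by transcript length stays open, and the effective lengths point to fragments 7.48 bases shorter at 25 °C. Whether carry-over of rRNA differed cannot be told apart from temperature, since 0 of 15 rRNA genes had a count. A difference between the temperatures in these RNAs also stays open, as untested.

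Genes of low abundance tended to be higher and abundant ones lower at 25 °C: the median log2 ratio was 0.30 in the lowest of 5 equal bins by abundance and -0.37 in the highest, a difference of 0.66. Without all genes of the 31 lists the difference was 0.54 (0.39 to 0.72), which argues against those lists as its sole source. Evenly spread background reads at 25 °C could lift low genes, and 0.37% of 2455 genes lay under 50% of the read density this needs. The 2455 leave out 52 intact genes with no read in either library, for which no effective length could be derived. The same density was missed by 0.73% at 13 °C, so the measure would have come out alike without background, and background and temperature cannot be told apart by it. The size also varied with the read filter: on 3768 genes filtered on their scaled mean the difference was 0.54. Whether selection by the filter makes up this change was not tested.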

How the results depend on the processing

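Choices among list members, copies and frameshifted genes were made after seeing the data. No paired analysis was possible because each temperature has 1 library. Pseudocounts and filters meant for a table without counts were not run, since counts were deposited. The 530 higher and 597 lower genes became 1166 and 264 with total protein-coding counts and 941 and 335 without the 20 most abundant genes. These scalings add 0.54 and 0.37 to every log2 ratio. A filter of 200 reads, which tests fewer genes, left 312 higher and 472 lower. The higher ones were then 39.8% of called genes, against 47.0% with the main filter. The 1.5-fold threshold gave 992 and 1067, and 4-fold 104 and 136. Under the other alternatives both counts stayed within 1.5 times. The 50 higher and 60 lower runs became 15 and 18 with a minimum of 5 genes and 141 and 29 with total scaling. A common factor for all genes leaves the percentiles of lists as they are, but under total scaling every median between -0.54 and 0 changes sign, among them 2 of lists outside the range of random lists, fatty acid synthesis to 0.010 and secretion to 0.13. With 200 reads, heat shock (-0.88) and fatty acid synthesis (-0.52) came inside the range of random lists. Pili and motility (1.52, on fewer than its 7 members) left it. Heat shock came inside with product names and symbols but not KEGG names (-0.85). Fatty acid synthesis came inside without dropped members (-0.53), while polyphosphate then left the range (0.55). Ribosomal proteins left the range with the deposited FPKM (-0.74), with 10 reads (-0.68) and with no filter (-0.68). The citric acid cycle (-0.49) and mobile elements (0.29) left it with 10 reads, and sugar transport (-0.78) with no filter. Where not stated, the cause was not tested. Under total scaling 103 of 118 named genes moved outside their counting intervals. Depth limits genes with few reads.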

Other observations

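The 9 gene groups here were chosen after the values had been seen, and all 9 are given. Of 94 genes matched as solute-binding proteins of transporters, 4 were at least 2-fold higher at 25 °C and 41 lower (median log2 ratio -0.83). Many of the 94 are annotated only as substrate-binding domain-containing proteins, a name that gives no transporter, so their function is uncertain. Of 99 permeases of ABC transporters 6 were higher and 49 lower (-0.96). Both medians lay below all 10000 matched random lists, and with total scaling, which adds 0.54, both stay below 0. GU243_08215, with 85334 and 10867 reads, and GU243_16540, with 38921 and 7946 reads, were among the most abundant. The 4 higher of these 94 genes were pstS, GU243_17860 (43 and 604 reads), GU243_11635 (101 and 446) and GU243_15295 (142 and 597). GU243_15295 is annotated only as a substrate-binding domain-containing protein. Of 36 acyl-CoA dehydrogenases, enoyl-CoA hydratases and thiolases, many of them annotated as glutaryl-CoA dehydrogenase or acetyl-CoA C-acetyltransferase, 0 were higher and 12 lower (-0.72, percentile 0.02). MFS transporters did not stand apart (9 of 95 higher, 18 lower, percentile 10.3), nor did glycosyltransferases (4 of 22 and 0, 92.5).

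Histidine degradation had 5 of 6 genes higher and 0 lower (3.37), and glycine cleavage with glycine, serine and threonine degradation 8 of 16 higher and 1 lower (1.40), both above all random lists. The genome carries a pair of gcvP genes. In the long run gcvP (feature 4519) had 693 and 8493 reads, while gcvP (feature 8111) had 3076 and 6794. Purine degradation had 6 of 12 higher and 0 lower (0.81, percentile 97.9), and 1 of the 12, GU243_10665, is a hippurate hydrolase that the pattern took in by its name. Transcriptional regulators of named families had 39 of 189 higher and 13 lower (0.36, percentile 99.99). Because these groups were picked from the same libraries, their positions are not independent evidence of their direction.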
